A study of Solanum lycopersicum with 12 samples.

How the data were processed

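RNA from the mesocarp of red ripe greenhouse-grown fruits of 4 tomato genotypes, 3 fruits each, was sequenced; the same material also served nuclear magnetic resonance measurements, which were not used here. The authors deposited 1 table of whole-number counts of reads per gene for 12 libraries. Its name speaks of a normalized object, but all values are whole and the totals differ between libraries, from 15207931 to 25320267, so the values were taken as raw counts. Per the submitters' processing notes, which list tools without their roles, FastQC, fastp 0.21, HISAT2 2.1.0, featureCounts of the Subread package, edgeR and R 4.0.3 were used. The genome build, annotation, strand setting and treatment of reads that match several places are not given in the sources used here. Reads of a gene and an overlapping or antisense gene, or of near-identical copies, may therefore not be separable, and alleles of the wild parent may map less well than those of the reference. Every gene in the deposited table has over 0.5 CPM in at least 3 libraries, so genes below that level were not analysed here. All 12 columns were matched to samples by their names, and 0 were left over.

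Groups came from the genotype in the labels. The main test was edgeR's quasi-likelihood F test on the counts, with TMM scaling (factors 0.884 to 1.24) and 1 mean per genotype over all 12 libraries, which share the estimate of spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. The filterByExpr filter removed 0 genes, leaving 17887. The common biological coefficient of variation was 0.309, with 8 residual degrees of freedom and a median of 3.99 prior degrees of freedom. The standard error is the log2 fold change divided by the square root of F. The 9 comparisons were Q against G, QxG against GxQ, each hybrid against each parent, each hybrid against the mid-parent and both hybrids against the mid-parent; the mid-parent is the mean of the fitted log values of Q and G. CPM are TMM-scaled, given as mean ± SD over libraries. For replicate correlations 0.5 was added to CPM before the log2. No pair of libraries held identical values, and within each genotype pairs differed far beyond sampling noise (chi-square per gene 15.4 to 142).

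Replicate numbers given in the labels were checked for pairing by the correlation of deviations from the group means. All 3 pairs of QxG and GxQ libraries that share a number were over 0.1 (0.111, 0.281 and 0.185), so these were treated as paired in an added fit with the number as a block in the hybrids; no other pair of genotypes had all 3 over 0.1.

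The design, the tests, the lists and the alternatives were fixed before the data were examined, except those named as added in the closing section. Genes were named by a rule: up to 6 called list genes with the largest rise and 6 with the largest fall per comparison with a mean of at least 5 CPM and no overlap between the libraries of the 2 sides (which chance gives for 10% of genes with 3 against 3 and 0.216% with 6 against 6), up to 3 called members of each list with the smallest adjusted p, and, for Q against G, RIN, NOR, PSY1, CYCB, PG2A, PL, E8, ACS2, ACO1, LIN5, TomLoxC and ALMT9, called or not. ALMT9 was not among the genes analysed here. One-parent transcripts have no names here, so 2 per parent were printed in place of the 3 planned.

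The table gives Solyc identifiers with version suffixes and no names. None of them matched the identifiers of the RefSeq gene table (assembly SLM_r2.1, 41476 genes; 0 matched). Names therefore rest on 15 lists of 218 genes written with their identifiers beforehand, of which 162 were in the table. The lists cover carotenoids, ripening and ethylene, cell wall, sugars, organic acids and GABA, phenylpropanoids, glycoalkaloids, volatiles, ascorbate, defence, heat shock, chloroplast, fruit size and shape, and seed and epidermis as other tissues. As a check, 141 symbols named exactly 1 RefSeq gene, and 135 of these lay on the chromosome of the identifier; 838 of 874 pairs on 1 chromosome stood in the same order. E8 was among those on another chromosome, so its name is less sure. Genes whose names in the lists were shorthand are printed by identifier. The values of 1 ripening gene are not reported here.

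Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 15 lists of a comparison; members called were counted over all genes and adjusted over the list alone. Genes were ordered by the numbers in their identifiers within chromosomes (17684 genes, 203 left out), and calls were permuted 10000 times. One-parent transcripts needed at least 1 CPM on average in a parent and 0 counts in every library of the other; 3 counts were taken as the floor, which is 0.119 to 0.197 CPM in a single library. Position relative to the parents was the departure from the mid-parent divided by the distance from the mid-parent to Q, with 2000 bootstrap draws over genes. Tests were tried on simulated data of 17887 genes, some of them changed 2-fold or 4-fold. For Q against G 31.0% and 87.0% of these were recovered, and 4.84% of calls were false. For both hybrids against the mid-parent 76.0% and 96.0% were recovered, and 4.40% of calls were false. Changed genes excluded those of lowest mean level, so recovery is not given for such genes. Each gene and library was drawn independently, so these shares do not cover libraries that stand apart from their genotype.

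Alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, a 2-fold minimum, an adjusted p under 0.01, DESeq2's Wald test, only the 2 groups compared in the fit, an arithmetic mid-parent, windows of 25 and 100 genes, and 0.5 and 5 CPM for one-parent transcripts. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.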

Results

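Gene expression was measured by RNA sequencing in the mesocarp, the fleshy middle layer of the wall, of red ripe tomato fruits from 4 genotypes. Querubín FCA (Q) and Gema FCA (G) are recombinant inbred lines, fixed lines bred from a cross of the cultivated tomato with its wild relative Solanum pimpinellifolium. The other 2 genotypes are their reciprocal hybrids, QxG and GxQ, made from the same parents with the order of the cross exchanged. Each genotype had 3 libraries, which the labels describe as separate fruits used as biological replicates. The table held whole-number read counts for 17887 genes. Total counts were 20471869, 20455220 and 19026890 in Q, 20973043, 15207931 and 25320267 in G, 23862296, 17928230 and 19070034 in QxG, and 18234869, 19956457 and 18738753 in GxQ. In the plot of principal components, which carry 30.01% and 22.4% of the variance of log2 CPM (counts scaled to a common library total), some libraries stood apart from the others of their genotype. The third Q library correlated with the first and second at r = 0.953 and 0.956 across genes, against 0.986 between those. The first QxG library had 1436 genes at 0 counts, against 31 to 338 in the other libraries, and correlated with the others of its genotype at 0.952 and 0.951. It had 77 genes at 1 to 4 counts, against 730 and 724 in those. Whether its low counts were set to 0 is not given in the sources used here, so a 0 in this library is not read as absence and low QxG means are uncertain. The 10 most abundant genes took 6.06% and 6.55% of the counts in the first and second Q library and 8.38% to 13.4% elsewhere. Genes are not independent replicates, so these correlations only describe the libraries.

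**Figure D1:**
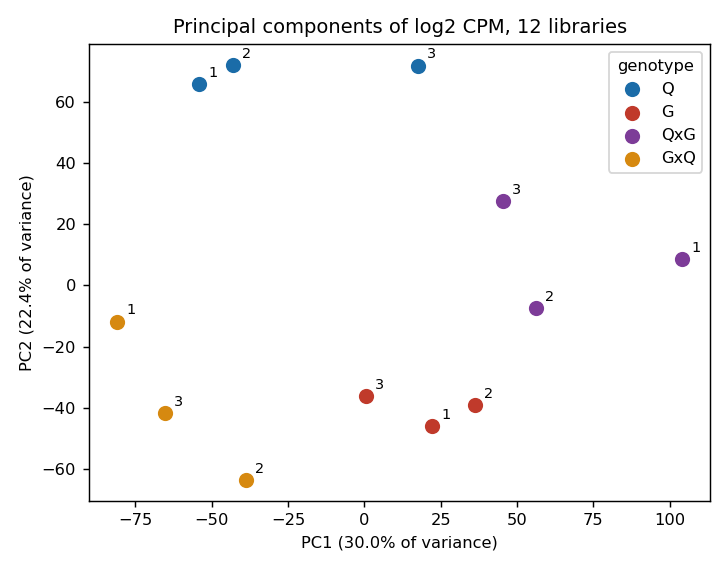
Positions of the 12 libraries on the first and second principal components of log2 CPM over 17887 genes, which carry 30.01% and 22.4% of the variance; colours mark the genotype and digits the replicate number. The third Q library lies away from the first and second Q libraries.

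The parental lines differed in 1308 genes, among them an invertase, a dioxygenase and a pectinesterase. TIV1, the vacuolar invertase that splits stored sucrose, averaged 1373 ± 480 CPM in Q and 13650 ± 1551 CPM in G (SD, n = 3 each), a 9.94-fold lower level in Q (log2 fold change -3.31, SE 0.392, adjusted p = 0.00122). CCD1A, a dioxygenase that cleaves carotenoids into volatile apocarotenoids, was 10.1-fold lower in Q, at 7.45 ± 0.719 against 75.1 ± 15.3 CPM (adjusted p = 2.13e-06). The pectinesterase gene Solyc07g064180 was 62.3-fold higher in Q, at 411 ± 143 against 6.56 ± 3.02 CPM (adjusted p = 0.00378). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1308 of 17887 genes between Q and G, 806 higher and 502 lower in Q.

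Among 22 measured genes of sugar metabolism and transport, 5 were higher and 1 was lower in Q, or 6 and 2 adjusted over the list alone. Both listed subunit genes of ADP-glucose pyrophosphorylase, which supplies starch synthesis, rose in Q: AGPL1 from 0.426 ± 0.140 CPM in G to 5.84 ± 3.08 CPM (adjusted p = 0.00805) and AGPS1 from 2.46 ± 0.718 to 17.7 ± 3.07 CPM (adjusted p = 0.0144). SUS1, a sucrose synthase, stood at 96.2 ± 60.9 CPM in Q and 23.4 ± 3.35 CPM in G (log2 fold change 2.04, adjusted p = 0.0108). HXK1, a hexokinase, and SUT4, a sucrose transporter, were also higher, with log2 fold changes of 1.48 and 0.98. The cell wall invertase LIN5 averaged 70.5 CPM in Q and 40.5 CPM in G and did not pass (adjusted p = 0.132). Of 10 genes of organic acid and GABA metabolism, 2 were higher and 2 lower in Q, with the same counts adjusted over the list alone. Aconitase Solyc12g005860 rose to 135 ± 5.19 CPM from 46.0 ± 7.34 CPM in G, and the glutamate decarboxylase GAD2, which makes GABA, rose to 36.9 ± 9.65 from 10.5 ± 0.345 CPM (adjusted p = 0.00251 and 0.00381). PEPCK1, which draws on organic acids for gluconeogenesis, fell by 2.04 on the log2 scale (adjusted p = 0.0344), and GAD1 fell by 0.72. HXK1, SUT4, GAD1 and the pectinesterase gene Solyc07g064170 below were named after their values were seen. Other genes follow the rule fixed beforehand, except those marked in the same way where they appear.

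The 21 measured carotenoid and isoprenoid genes held 3 members lower in Q and 0 higher, also when adjusted over the list alone. Besides CCD1A these were its neighbour CCD1B, at 343 ± 76.4 against 715 ± 93.0 CPM, and the phytoene desaturase PDS, at 106 ± 18.7 against 221 ± 10.0 CPM (adjusted p = 0.00792 and 0.0339). The camera test placed this list lower in Q relative to other genes (adjusted p = 0.00417), a call that was lost with an estimated correlation between its genes (adjusted p = 0.625 with an estimated correlation). The third Q library lay nearer G for some members, such as the synthase GGPPS2 at 224 CPM, against 46.7 and 44.3 in the first and second and 174 to 231 in G. Without that library the list median moved from -0.35 to -0.51 on the log2 scale (camera adjusted p = 7.16e-05). GGPPS2 was chosen after its values were seen. PSY1, the first committed enzyme of carotenoid synthesis, stood at 6617 ± 2510 CPM in Q, with 9515 CPM in the third library, and 8968 ± 243 CPM in G (adjusted p = 0.406), and the lycopene cyclase CYCB at 6.04 ± 1.82 and 4.23 ± 0.461 CPM (adjusted p = 0.405).

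Of 29 ripening and ethylene genes, 2 were lower in Q and 0 higher, with the same counts adjusted over the list alone. ACS1A, which makes the ethylene precursor, fell by 3.16 on the log2 scale (6.65 ± 5.47 against 60.2 ± 13.8 CPM, adjusted p = 0.0156), and CTR1, a negative regulator of ethylene signalling, fell by 1.22 (adjusted p = 0.00663). The ripening regulators RIN and NOR had log2 fold changes of -0.31 and 0.24 (adjusted p = 0.406 and 0.623). The ripening ethylene genes ACS2, ACO1 and E8 had 0.99, 0.70 and -0.07 (adjusted p = 0.290, 0.497 and 0.923). The third Q library held 2098 CPM of ACS2 and 3217 CPM of ACO1, against 616 and 669 CPM of ACS2 and 963 and 855 CPM of ACO1 in the first and second. Of 13 cell wall genes, 2 were higher and 2 lower, with the same counts adjusted over the list alone. The polygalacturonase beta subunit gene Solyc05g005560 rose by 6.52 on the log2 scale (33.6 ± 37.5 against 0.338 ± 0.229 CPM, adjusted p = 0.0145). The endoglucanase CEL1 and the pectinesterase Solyc07g064170 fell by 3.47 and 1.00 (adjusted p = 0.0198 and 0.0421). The polygalacturonase PG2A and the pectate lyase PL, which loosen pectin in ripening fruit, had log2 fold changes of 0.27 and 0.19 (adjusted p = 0.776 and 0.713). In the third Q library PG2A stood at 7549 CPM, against 1565 and 1918 CPM in the first and second. Neighbouring copies such as CCD1A and CCD1B or the pectinesterase genes may share reads, so the split of counts between them is uncertain.

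Single members moved in other lists. The lipase LIP8, tied to fatty acid volatiles, fell in Q by 1.04 on the log2 scale (70.4 ± 1.27 against 144 ± 4.94 CPM), as the 1 called member of 12 volatile genes (1 higher and 2 lower adjusted over the list alone); TomLoxC, the volatile lipoxygenase, had a log2 fold change of -0.12 (adjusted p = 0.876). Chalcone isomerase CHI rose 12.1-fold to 3.15 ± 0.991 CPM, as 1 of 11 phenylpropanoid genes. GAME5, a glycosyltransferase of glycoalkaloid synthesis, fell by 2.12, as 1 of 4 glycoalkaloid genes. Of 8 chloroplast genes, APRR2L, tied to plastid development, and the chlorophyll a/b-binding protein gene Solyc03g005760 rose by log2 fold changes of 1.46 and 1.58 (2 higher and 1 lower adjusted over the list alone). CER6, of cuticular wax synthesis, rose by 3.91, as 1 of 2 epidermis markers. For phenylpropanoid, glycoalkaloid and epidermis genes the counts were the same adjusted over the list alone. By edgeR no member was called among 9 ascorbate genes (3 higher adjusted over the list alone), 6 defence, 10 heat shock, 2 fruit size and shape and 3 seed genes (0 adjusted over the list alone in each). At an unadjusted p under 0.05 these lists held 4, 1, 1, 0 and 0 genes, and DESeq2 called 3, 1, 1, 0 and 0. No list but the carotenoid list passed camera in this comparison.

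The count was 335, 392 and 459 without the first, the second and the third G library, 549 and 494 without the first and second Q library, and 2207 without the first QxG library, which enters the estimate of spread; without that library and the third Q library together it was 2939, with only the parents in the fit 2553, and by DESeq2 2643. Calls ended without any 1 of the G libraries for Solyc05g005560 and AGPS1 (highest adjusted p = 0.0721 and 0.0661), without the first G library for SUS1 and ACS1A (0.0575 and 0.0541), and without any of 5 or 6 parental libraries for PDS, CEL1, CER6, Solyc03g005760, PEPCK1 and GAME5 (0.0775 to 0.135).

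**Figure D2:**
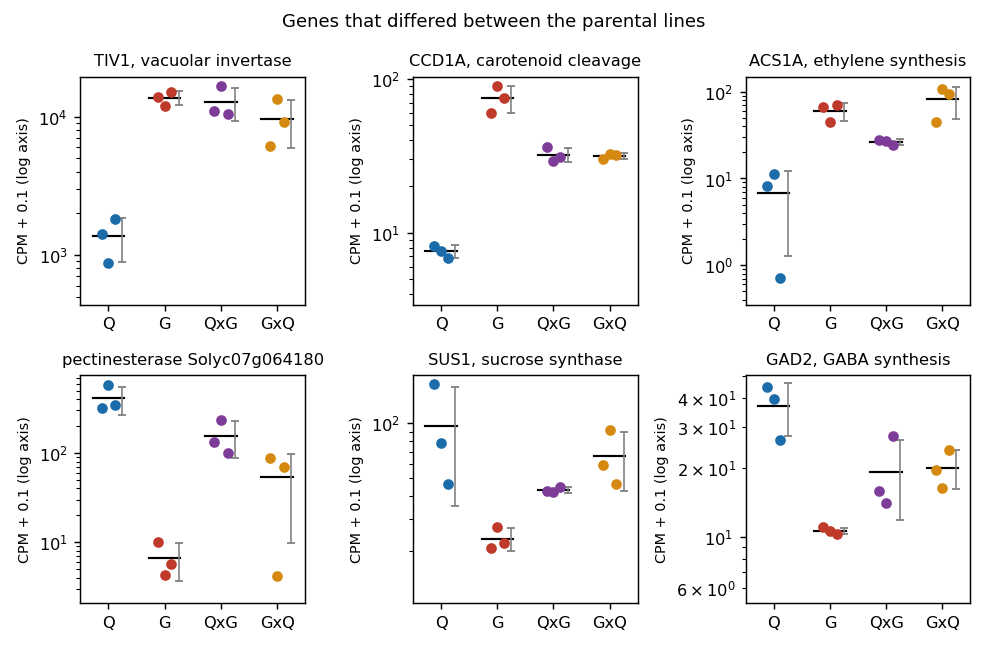
CPM + 0.1 on a log axis for 6 genes that differed between the parental lines, with 1 point per library, a black line at the mean of 3 libraries and a grey bar of 1 SD. TIV1 averaged 1373 CPM in Q and 13650 CPM in G, and the pectinesterase gene Solyc07g064180 averaged 411 and 6.56 CPM.

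Some transcripts were found in 1 parent alone. With a mean of at least 1 CPM in a parent and 0 counts in all 3 libraries of the other, 25 genes were found in Q and 10 in G. Solyc05g006370 averaged 18.2 ± 1.80 CPM in G, at least 364-fold higher than the 3 counts that 0 allows over the 3 Q libraries together. It stood at 48.1% of the G level in QxG and 54.5% in GxQ. Solyc05g006140 averaged 13.3 ± 1.42 CPM in G, at least 266-fold higher. In Q, Solyc09g091615 averaged 30.5 ± 3.24 CPM and Solyc10g086780 averaged 24.4 ± 2.98 CPM, at least 625-fold and 501-fold higher than in G. These stood at 27.0% and 47.6% of the Q level in QxG, and at 20.7% and 37.2% in GxQ. The median over the genes found in G was 24.9% of the parent's level in QxG and 21.5% in GxQ, and over those found in Q 14.6% and 15.2%. In QxG, 5 of the 10 and 8 of the 25 had counts in all 3 libraries, and in GxQ 10 and 17. In the first QxG library 5 and 16 were at 0, and without it the QxG medians were 24.3% and 21.8%. With a minimum of 5 CPM, 7 genes were found in Q and 4 in G. Limits from 0 counts cover counting error only.

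Genes that differed between the parents lay near each other along the chromosomes. Of neighbouring pairs among 17684 genes ordered by their identifiers, 141 had both members called, against 94.0 ± 8.92 when calls were permuted over genes (ratio 1.50, permutation p = 0.0001, the smallest that 10000 permutations can give). The excess reached far: pairs 10 and 30 tested genes apart were called together 1.45 and 1.32 times as often as by chance, and pairs 200 apart 0.958 times. In windows of 50 tested genes, the highest count was 14 called genes on chromosome 5 between Solyc05g005800 and Solyc05g006560, a stretch that also holds Solyc05g006370 and Solyc05g006140. A window on chromosome 7 from Solyc07g063465 to Solyc07g064270, which holds the pectinesterase genes above, had 13, as did a window on chromosome 8 from Solyc08g077290 to Solyc08g077990 and 1 each on chromosomes 9 and 10. Of 348 windows, 6 held more than the 12 that mark the 95th percentile of permuted maxima. For the reciprocal hybrids the ratio was 1.51 for neighbours, and 3776 pairs 10 to 30 genes apart compared with 3794 when permuted. For both hybrids against the mid-parent it was 1.17 for neighbours (permutation p = 0.0023), and 4808 pairs compared with 4844.

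**Figure D3:**
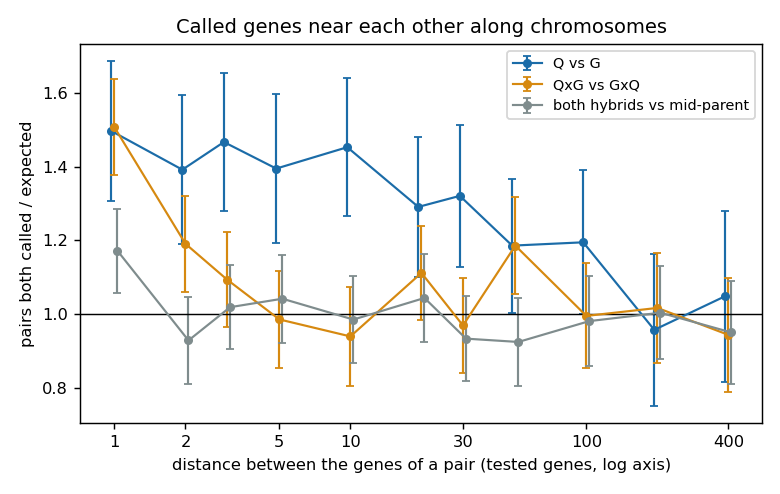
Pairs of genes with both members called, divided by the number expected, against their distance in tested genes on a log axis; lines mark 3 comparisons and bars 2 permuted SD. For the parental lines the ratio was 1.50 for neighbours, 1.32 at 30 genes and 0.958 at 200 genes.

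The reciprocal hybrids, which share their parents and differ in the order of the cross, differed in 1815 genes, among them a lipoxygenase, an aconitase and a small heat shock gene. LOXD, a lipoxygenase of jasmonate synthesis, averaged 3.79 ± 2.60 CPM in QxG and 194 ± 87.2 CPM in GxQ (SD, n = 3 each; log2 fold change -5.69, SE 0.867, adjusted p = 0.00152). Aconitase Solyc12g005860 was 10.1-fold lower in QxG, at 74.2 ± 21.7 against 748 ± 77.5 CPM (adjusted p = 3.93e-05). HSP21, the small heat shock protein of plastids, was higher in QxG. It averaged 3223 ± 1395 CPM in QxG and 699 ± 330 CPM in GxQ (adjusted p = 0.00818). The edgeR quasi-likelihood test called 1815 genes, 476 higher and 1339 lower in QxG. These became 778 and 1427 without the third Q library, 1012 and 1506 without that and the first QxG library, and 986 and 1729 by DESeq2.

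Among genes lower in QxG, AADC1A, a decarboxylase that starts the phenylalanine-derived volatiles, stood at 0.258 ± 0.347 against 19.1 ± 12.3 CPM (log2 fold change -6.27, adjusted p = 0.00481). A phenylalanine ammonia-lyase gene, Solyc09g007920, stood at 1.41 ± 1.30 against 41.4 ± 16.7 CPM (adjusted p = 0.00481), and the fruit shape regulator OVATE at 8.73 ± 3.64 against 44.0 ± 10.2 CPM (adjusted p = 0.00102). INVINH1, an inhibitor of invertases, fell by 1.85 on the log2 scale (adjusted p = 0.00104). The ripening factor FUL2 and the ethylene-forming oxidase ACO5 fell by 0.58 and 3.18 (adjusted p = 0.0139 and 0.0273), the 2 called members of 29 ripening genes. Fruits of the same genotype varied in some genes too. Single Q libraries held 55.2, 35.4 and 5.11 CPM of LOXD and 9.88, 5.01 and 0.824 CPM of AADC1A. They held 17.7, 11.2 and 0.989 CPM of Solyc09g007920, but 136, 129 and 140 CPM of aconitase Solyc12g005860. The labels name no harvest, so harvest or handling cannot be told apart from genotype in any comparison. The order of the cross was not tested as the cause.

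Of 10 heat shock genes, 4 were higher in QxG and 0 lower, or 5 and 0 adjusted over the list alone. HSP90 averaged 6661 ± 3060 against 1058 ± 229 CPM, HSP101 3749 ± 1009 against 1256 ± 227 CPM, and the small heat shock gene Solyc06g076540 1052 ± 584 against 200 ± 89.4 CPM (adjusted p = 0.0143, 0.00968 and 0.0178). Camera placed this list higher in QxG (adjusted p = 8.32e-05; adjusted p = 0.624 with an estimated correlation). Of 13 cell wall genes, 3 were higher and 0 lower, or 4 and 0 adjusted over the list alone. PL averaged 2058 ± 283 against 653 ± 66.9 CPM (log2 fold change 1.66, adjusted p = 0.00364), and the expansin EXP1 and the mannanase MAN4 rose by log2 fold changes of 1.76 and 3.94 (adjusted p = 0.0346 and 0.0293). The camera call for this list (adjusted p = 0.00599) and that for carotenoid genes (adjusted p = 0.0214) were lost too (adjusted p = 0.624 and 0.669 with an estimated correlation). The carotenoid call also ended without the second or the third QxG or the first GxQ library (adjusted p = 0.0826, 0.103 and 0.201). Carotenoid genes had 2 of 21 members higher, CCD1B and the geranylgeranyl diphosphate synthase GGPPS3, with log2 fold changes of 0.70 and 0.67, and 0 lower. The chlorophyll a/b-binding protein gene Solyc03g005760 rose by a log2 fold change of 1.58, as 1 of 8 chloroplast genes (5 higher and 1 lower adjusted over the list alone). AAT1, an alcohol acyltransferase that makes volatile esters, rose by 1.01, so that of 12 volatile genes 1 was higher and 2 were lower. By edgeR no member was called among 4 glycoalkaloid genes (1 higher and 2 lower adjusted over the list alone), 9 ascorbate, 6 defence, 3 seed and 2 epidermis genes (0 adjusted over the list alone in each). At an unadjusted p under 0.05 these lists held 3, 0, 1, 1 and 0 genes, and DESeq2 called 1 glycoalkaloid gene and 0 in the others. For lists where no second count is given, the counts adjusted over the list alone were the same. With the replicate number as a block in the hybrids, 1 more member was called in each of 6 lists: carotenoid (1 lower), ripening (1 higher), acid and GABA (1 higher), defence (1 higher), phenylpropanoid (2 lower) and chloroplast genes (2 higher).

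Without the third GxQ library the count fell to 1127, and with only the hybrids in the fit it was 1143. Calls ended without 1 library of either hybrid for MAN4, HSP90, Solyc06g076540, Solyc03g005760, AAT1, FUL2 and ACO5, and also without 1 G library for EXP1, CCD1B and GGPPS3 (highest adjusted p = 0.0591 to 0.131); for HSP90 the libraries were the third QxG and the first GxQ. LOXD, AADC1A and Solyc09g007920, low in QxG, stayed called without the first QxG library.

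**Figure D4:**
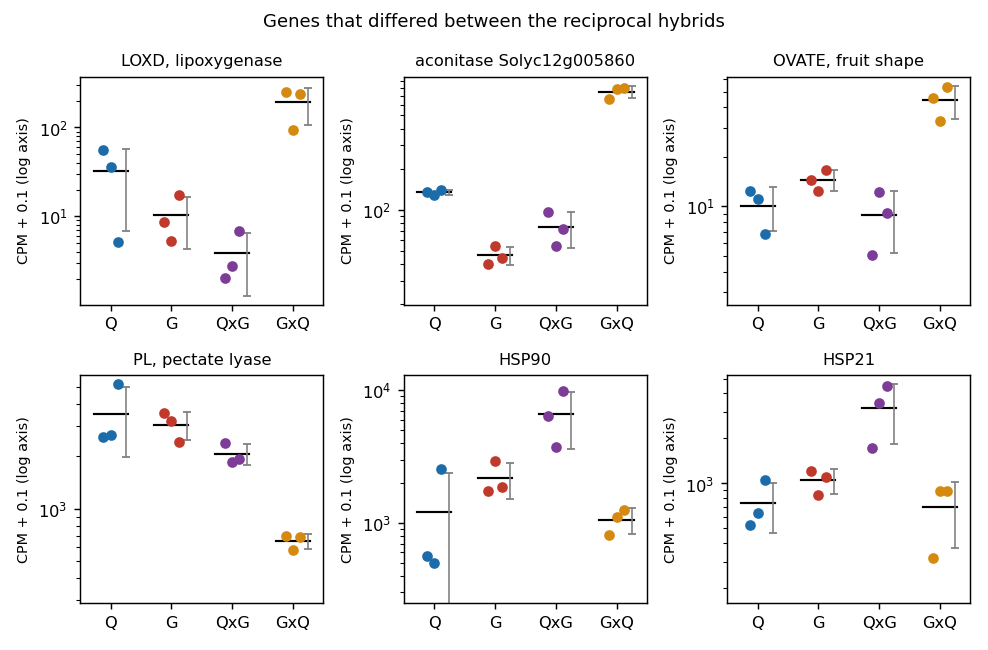
CPM + 0.1 on a log axis for 6 genes that differed between the reciprocal hybrids, with 1 point per library, a black line at the mean of 3 libraries and a grey bar of 1 SD. LOXD averaged 3.79 CPM in QxG and 194 CPM in GxQ, and HSP90 averaged 6661 and 1058 CPM.

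Both hybrids together were compared with the mid-parent, the mean of the parents on the log scale. TIV1, the vacuolar invertase, averaged 11140 ± 3611 CPM in the hybrids (SD, n = 6), against 1373 CPM in Q and 13650 CPM in G. It lay above the mid-parent by 1.35 on the log2 scale (SE 0.258, edgeR adjusted p = 0.00852). The parental libraries together averaged 7512 CPM, so its departure from the arithmetic mean of the parents was smaller. GGP1 and GGP2, which encode the main control step of ascorbate synthesis, fell by 0.88 and 0.98 (adjusted p = 0.00230 and 0.00733); GGP1 averaged 340 ± 37.1 CPM in the hybrids and 629 ± 93.2 CPM in the parents. PL fell by 1.49 (1355 ± 792 against 3258 ± 1044 CPM, adjusted p = 0.00219), and GAME5 by 2.54 (adjusted p = 0.00333). The edgeR quasi-likelihood test called 2045 genes, 948 above and 1097 below the mid-parent. Which side held more genes was not stable. The larger side turned under RLE scaling, with 1058 above and 1015 below. Without the first Q, the second Q and the third GxQ library it turned too, with 649 and 586, 564 and 557, and 722 and 702. By DESeq2 the sides were nearly equal, at 1609 and 1615.

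Of 29 ripening genes, 2 were above the mid-parent and 4 below, or 2 and 5 adjusted over the list alone. The ethylene receptor ETR2 averaged 72.8 CPM in the hybrids and 37.5 CPM in the parents (log2 fold change 0.98, SE 0.142, adjusted p = 0.00258), and FUL2 123.5 ± 28.9 and 85.5 ± 5.85 CPM (adjusted p = 0.00673), while the receptor ETR4 fell by 0.88 (adjusted p = 0.0200) and the ethylene synthesis genes ACS4 and ACO4 fell by 1.42 and 0.91. Of 9 ascorbate genes, 1 was above, the ascorbate peroxidase APX1 (log2 fold change 0.89, adjusted p = 0.0121), and 3 were below, GGP1, GGP2 and GME1, of the same pathway, which fell by 0.44. Of 22 sugar genes, TIV1 was above and 4 were below, SUT4, the fructokinase FRK1, the invertase LIN7 and HXK1 at -0.93, -0.58, -0.87 and -0.81 (adjusted p = 0.0108, 0.0105, 0.0237 and 0.0398). Of 10 acid and GABA genes, 2 were above, aconitase Solyc12g005860 by 1.58 (adjusted p = 0.000304) and GAD1 by 0.62 (adjusted p = 0.0152). The aconitase averaged 74.2 CPM in QxG and 748 CPM in GxQ, so its departure was unequal in the hybrids. Some other genes called for both hybrids together were called in GxQ alone. Their log2 departures in QxG and GxQ were -0.66 and -2.32 for PL, -0.99 and -4.93 for MAN4, and 0.22 and 0.79 for FUL2. For AAT1 they were -0.12 and -1.12, and for GGPPS3 -0.18 and -0.85. ETR2, LIP8 and GGP1 were called in each hybrid singly.

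Of 10 heat shock genes, 4 were above and 0 below, among them the small heat shock genes Solyc06g076560 and Solyc06g076520 at 1.55 and 1.46 (adjusted p = 0.0102 and 0.0114) and Solyc08g062340, 4.30-fold above (adjusted p = 0.0284); the fourth was Solyc06g076570 at 0.97. Camera placed this list above the mid-parent (adjusted p = 0.0102; adjusted p = 0.506 with an estimated correlation) and called no other list here; without the third QxG library the call ended (adjusted p = 0.0518). For QxG alone, with 7 members above and 0 below, camera gave adjusted p = 8.99e-07 (adjusted p = 0.737 with an estimated correlation), and for GxQ alone, with 1 above and HSP101 below, 0.786. The camera call for the difference between the hybrids was lost with an estimated correlation too (adjusted p = 0.624). Of 21 carotenoid genes, 1 was above and 3 below, or 1 and 4 adjusted over the list alone. The isomerase ZISO and GGPPS3 fell by 0.87 and 0.51 (adjusted p = 0.0137 and 0.0286), and NCED1, of abscisic acid synthesis, fell by 0.91. NCED1, ACS4, ACO4, GME1, HXK1 and Solyc06g076570 were named after their values were seen. CCD1A lay above by 0.43 (adjusted p = 0.0321), but -0.37 against the arithmetic mean of the parents. Cell wall genes had 0 above and 2 of 13 below, PL and MAN4 (1 above and 6 below adjusted over the list alone). LIP8 and 4-coumarate:CoA ligase were above by 0.81 and 0.89, and AAT1 and the glycoalkaloid transporter GORKY fell by 0.62 and 0.65. PSBS, of photosystem II, and CER6 fell by 2.36 and 2.74. This left 1 above and 1 below of 12 volatile genes, 1 above of 11 phenylpropanoid genes, 2 below of 4 glycoalkaloid genes, 1 below of 8 chloroplast genes (3 adjusted over the list alone) and 1 below of 2 epidermis genes. By edgeR no member was called among 6 defence genes (3 above adjusted over the list alone), 2 size and shape genes (1 above) and 3 seed genes (1 below); at an unadjusted p under 0.05 they held 3, 1 and 1 genes, and DESeq2 called 3, 1 and 1. For lists with no second count given, the counts adjusted over the list alone were the same.

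The count was 1235 and 1121 without the first and second Q library, 1146, 1272 and 1002 without the first, the second and the third G library, 1345 without the third QxG library, 3649 without the first QxG and the third Q library together, and 3224 by DESeq2. Calls ended without at least 1 single library for LIN7, GGPPS3, CCD1A, PSBS, CER6, AAT1, Solyc08g062340 and GORKY, with highest adjusted p from 0.0615 to 0.110; AAT1 kept its call without only the second GxQ library.

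Against single parents, both hybrids had genes outside the parental range, and GxQ had 601 above both parents where QxG had 162. CCD1A lay between the lines, at 31.8 ± 2.28 CPM over the 6 hybrid libraries against 7.45 CPM in Q and 75.1 CPM in G. By edgeR, QxG differed from Q in 1709 genes (651 higher, 1058 lower) and from G in 1521 (561 and 960), and GxQ differed from Q in 2780 (1455 and 1325) and from G in 2205 (1250 and 955). For QxG against G these were 657 and 833 under RLE scaling and 1329 and 1440 by DESeq2. For GxQ against Q the larger side turned under the 1 CPM filter (1332 higher, 1407 lower), with a 2-fold minimum (718 and 913), without the third Q library (1029 and 1056), without the first, the second and the third QxG library (1824 and 2004, 1273 and 1329, 1287 and 1336) and without the first QxG and the third Q library together (1765 and 1895). Below both parents were 375 genes in QxG and 378 in GxQ. The first QxG library, with 1436 genes at 0 counts, may lower QxG means, so the contrast of 162 with 601 genes is uncertain. Without it QxG had 688 genes higher and 885 lower than Q, and 676 higher and 870 lower than G. In 20 simulations of all libraries with additive hybrids, at most 2 genes lay above or below both parents in either hybrid. Each gene and library was drawn independently, so no simulated library stood apart as the first QxG and the third Q library do. The simulation therefore does not cover genes placed outside the parents by such libraries. Independent lists would share 20.4 and 56.8 genes above and below for QxG, and 102 and 70.7 for GxQ, and part of the excess may come from the hybrid libraries shared by both comparisons. Called between the parents were 20 genes in QxG and 29 in GxQ, while 964 and 1197 differed from G only and 1152 and 1772 from Q only; a missed call does not show equal levels. Against the mid-parent singly, QxG differed in 1522 genes (602 above, 920 below; 730 and 841 under RLE scaling, 640 and 677 without the first QxG library, and 1678 and 1562 without that and the third Q library) and GxQ in 2818 (1694 above, 1124 below). The count for QxG was 739, 763 and 2536 without the first, the second and the third Q library, 810 and 685 without the first and the third G library and 368 without the third QxG library, and that for GxQ was 1872, 1836 and 1455 without the first, the second and the third GxQ library. Outside both parents, the 537 genes of QxG became 156, 170 and 853 without the first, the second and the third Q library, 216, 331 and 161 without the first, the second and the third G library and 131 without the third QxG library. The 979 of GxQ became 516 without the second Q library, 475, 439 and 569 without the first, the second and the third G library and 625 and 465 without the first and the third GxQ library.

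Over the 1308 genes that differed between the lines, the median position of QxG, from -1 at G to 1 at Q, was 0.0455 (95% bootstrap range over genes -0.0333 to 0.0959), and 78.6% of its values lay between the parental means. GxQ lay nearer G, at -0.151 (-0.216 to -0.0610), with 69.5% between. The latter was 0.0642 without the second GxQ library and -0.431 without the first, -0.293 without the first Q library and -0.235 without the second G library; the position of QxG ran from -0.262 without the third Q library to 0.186 without the second QxG library, and was -0.377 without the first QxG and the third Q library together. Counts against single parents moved by over 1.5 times without single libraries: for QxG against Q, 310, 387 and 2606 without the first, the second and the third Q library and 985 and 759 without the second and the third QxG library; for QxG against G, 488, 722 and 342 without the first, the second and the third G library and 363 without the third QxG library; for GxQ against Q, 1696 and 1258 without the first and second Q library and 1555 and 1444 without the second and the third GxQ library; and for GxQ against G, 917, 777 and 1163 without the first, the second and the third G library and 1179 and 1177 without the first and the third GxQ library.

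**Figure D5:**
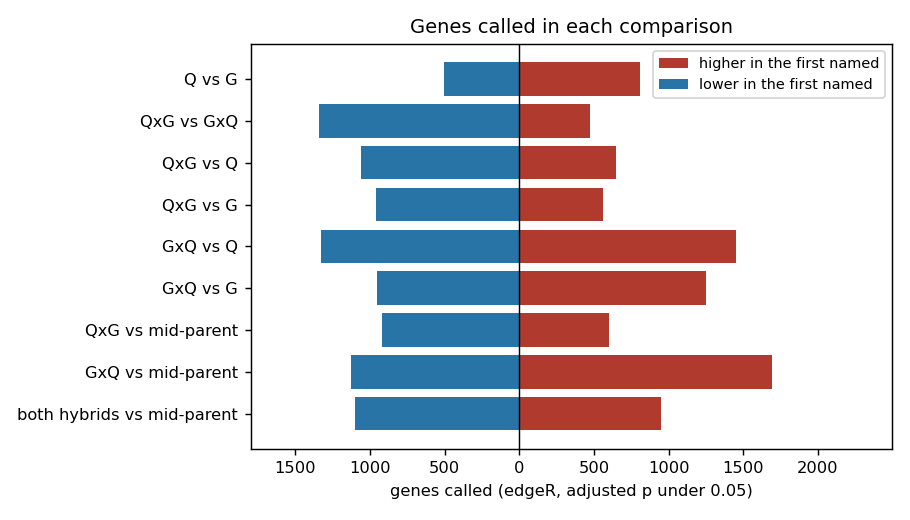
Number of genes called by edgeR's quasi-likelihood test in each of 9 comparisons, with genes higher in the first-named group to the right and lower to the left. The bars run from 1308 genes for Q against G to 2818 for GxQ against the mid-parent.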

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

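All tests of explanations in this part were chosen after the pattern was seen; the comparisons, the list tests and the counts of other splits of the libraries were chosen before.

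When the departures of the reciprocal hybrids from the mid-parent are compared, the mid-parent cancels, which leaves the test of QxG against GxQ above. By edgeR's quasi-likelihood test these departures differed in 1815 genes. By camera this also held for heat shock (adjusted p = 8.32e-05), cell wall (0.00599) and carotenoid genes (0.0214), none of which held with an estimated correlation (adjusted p = 0.624, 0.624 and 0.669 with an estimated correlation). Some genes rose above the mid-parent in GxQ without a call in QxG. The difference of QxG minus GxQ was -5.69 for LOXD (departures of -2.28 in QxG and 3.41 in GxQ), -6.27 for AADC1A (-2.79 and 3.49), -4.90 for phenylalanine ammonia-lyase Solyc09g007920 (-2.11 and 2.79), -3.33 for aconitase Solyc12g005860 (-0.09 and 3.25), -2.34 for OVATE (-0.47 and 1.87), -3.18 for ACO5 (-0.93 and 2.25) and -0.58 for FUL2 (0.22 and 0.79). INVINH1 was called in both, at -0.84 in QxG and 1.02 in GxQ, with a difference of -1.85. Its call in QxG was lost without any 1 of 8 libraries (edgeR, highest adjusted p = 0.177). In GxQ it was lost without the third GxQ library (adjusted p = 0.0509). Others fell below the mid-parent in GxQ without a call in QxG, with differences of 1.66 for PL, 3.94 for MAN4, 1.76 for EXP1, 1.58 for HSP101, 1.01 for AAT1, 1.58 for the chlorophyll a/b-binding gene Solyc03g005760 and 0.67 for GGPPS3. HSP90, HSP21 and the small heat shock gene Solyc06g076540 rose in QxG without a call in GxQ, with differences of 2.65, 2.21 and 2.40. CCD1B was called in neither, with a difference of 0.70. These are log2 values. As the labels name no harvest, harvest or handling of the fruits stays open for all these differences, beside the order of the cross.

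Heat shock genes stood above the mid-parent in QxG, with 7 of 10 members called and a median of 1.82 on the log2 scale. A single QxG library is argued against: the lowest median without 1 of them was 1.61. Without the third QxG library no member was called by edgeR, with a median that moved from 1.82 to 1.61 while the count over all genes fell from 1522 to 368; without the second, 5 were called. Reads shared among the small heat shock genes on chromosome 6 are also argued against as the only cause, since 3 of the 6 members outside that group were called above the mid-parent. Within the group all 4 members were called, and for these shared reads stay open. In the QxG libraries Solyc06g076560 stood at 4085, 8357 and 10190 CPM and Solyc06g076520 at 4132, 8158 and 9749 CPM. The 7 calls may therefore count the same signal more than once. Harvest or handling of the QxG fruits stays open for the 7 called members, as the labels name no harvest, and cannot be told apart from the genotype, which stays open too.

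Genes called between Q and G lay near each other along chromosomes. Reads shared between neighbouring copies are argued against as the only cause. Pairs 10 to 30 tested genes apart were called together 1.31 times as often as when permuted. For direct neighbours shared reads stay open: 71.6% of the 141 called pairs moved in the same direction, and 80.1% of 276 between the reciprocal hybrids. These shares have unlike chance levels and are not compared. Of all calls, 61.6% were higher in Q for the parents, but 26.2% were higher in QxG for the hybrids. Stretches of chromosome inherited from different parents of the original cross are consistent with an excess of 14.5 permuted SD at that distance for Q against G and none for both hybrids against the mid-parent (4808 pairs against 4844). Loss of reads from alleles of 1 species stays open: over pairs up to 30 genes apart, 54.6% moved in the same direction, against 52.7% when directions were permuted, a gap of 2.15 permuted SD that does not decide; for pairs 10 to 30 apart it was 53.3% against 52.8%, a gap of 0.525.

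The third Q library stood apart from the first and second. In CPM it held 21060 of LOXB, against 4698 and 4406 in the first and second and 21190 to 42400 in the other genotypes, and 4021 of CEL2, against 780 and 672; all 10 heat shock genes were above both, at 1.80 to 7.97 times their mean. LOXB and CEL2 were chosen after their values were seen. Other lists moved too: 16 of 21 carotenoid genes were above both the first and second Q library, and 4 below both. These counts were 9 and 3 of 13 cell wall, 9 and 3 of 12 volatile, 19 and 9 of 29 ripening and 9 and 10 of 22 sugar genes. Relative to the mean of the first and second, cell wall genes ran from 0.0310 to 8.32 times (median 2.00). Ripening genes ran from 0.0625 to 3.94 times (median 1.31). A mislabelled library is argued against: of 30 transcripts with at least 1 CPM in the first and second Q library and 0 counts in G, 29 had counts in the third, and all 10 of the transcripts found in G but not in those were at 0 in it. A difference in depth is argued against too, as its total of 19.0 M counts lies within the range of the other genotypes, 15207931 to 25320267 counts. RNA from seed in the third Q library stays open: 2 of the 3 measured seed genes were above both, OLE2 at 126 CPM against 16.8 and 15.3 (59.7 to 86.1 in G) and OLE3 at 3.19 against 1.98 and 1.14, while VIC2 stood at 1.04 against 1.34 and 1.47, and 3 genes of 8 listed, all 3 with counts in every G library too, are too few to decide. No biological explanation was tested, since the labels give the fruits no difference within a genotype, so biological differences between the Q fruits stay open.

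With 3 libraries against 3, 10 splits exist, too few for a share under 0.05. The real count and the highest other were 1308 and 0 for Q against G, 1815 and 0 for QxG against GxQ (4 of its splits, the real one among them, part all 3 numbered pairs and the other 6 part 1), 1709 and 154 for QxG against Q, 1521 and 0 for QxG against G, 2780 and 34 for GxQ against Q, and 2205 and 0 for GxQ against G. Among 100 splits of the libraries compared, only the real split (1 of 100) reached its count against the mid-parent. The real count and the highest other were 1522 and 846 for QxG, 2818 and 1995 for GxQ, and 2045 and 252 for both hybrids. Splits that mix genotypes add differences between genotypes to the spread, which lowers their counts, so this share cannot exclude chance. The 846 and 1995 came from splits that kept the hybrids in place and mixed Q with G. Such splits leave the mid-parent nearly unchanged, so they repeat almost the real contrast and give no level expected by chance.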

How the results depend on the processing

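Tests chosen after the data were seen are the fit without the first QxG and the third Q library, the block in the hybrids only, list tests without single libraries, one-parent transcripts without the first QxG library, and pairs 2 to 400 genes apart. Of 67 called results for named genes, 39 stayed called in the same direction without each library in turn and under RLE scaling, the 1 CPM filter, the block, DESeq2 and, where run, only the 2 groups in the fit; 28 were lost without at least 1 library. At an adjusted p under 0.01, 38 of these 67 were no longer past the threshold, and with a 2-fold minimum 20. No filter gave the same result, since filterByExpr removed 0 genes. RLE scaling and the 1 CPM filter moved no count of called genes by over 1.5 times. In windows of 25, 50 and 100 genes the highest count was 9, 14 and 26, and 3, 6 and 7 windows were above the permuted limit. RLE moved the median over genes by at most 0.0448 on the log2 scale. Over all genotypes, 5 of 18 pairs that share a number had correlated deviations over 0.1 (-0.246 to 0.281), among them all 3 of QxG with GxQ, and 6 of 12 libraries correlated best with their own number. With the replicate number as a block, counts were 1320 for Q against G, 1709 for QxG against GxQ and 1987 for both hybrids against the mid-parent, and 5 list tests passed in these 3 comparisons, as without it; PSBS and GORKY in both hybrids lost their calls. With the number as a block in the hybrids only, QxG against GxQ gave 2169 genes, all 19 named calls held, the same 3 lists passed camera and 6 lists gained 1 called member each; with only the hybrids in that fit it gave 1243, and CCD1B, GGPPS3 and FUL2 lost their calls. DESeq2 left 32 genes with no adjusted p.

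With an adjusted p under 0.01, counts fell to 282 for Q against G, 848 for QxG against GxQ, 241 for QxG against Q, 254 for QxG against G, 756 for GxQ against Q, 534 for GxQ against G, 272 for QxG, 933 for GxQ and 517 for both hybrids against the mid-parent, 70 and 210 genes outside both parents in QxG and GxQ, and a median position of -0.236 for GxQ. A 2-fold minimum gave 1119, 884, 1631 and 1338 for QxG against Q, QxG against G, GxQ against Q and GxQ against G, 780, 1373 and 611 for QxG, GxQ and both against the mid-parent, and 339 and 545 genes outside both parents in QxG and GxQ. These stricter thresholds lower counts by construction. DESeq2 gave 2643 for Q against G, 3085 and 2769 for QxG against Q and G, 3379 for GxQ against G, 2858 and 3224 for QxG and both hybrids against the mid-parent, and 1079 and 1598 outside both parents. Without the first QxG and the third Q library, counts were 2939 for Q against G, 3739 and 2682 for QxG against Q and G, 3919 for GxQ against G, 3240 and 3649 for QxG and both hybrids against the mid-parent, 1262 outside both parents in QxG, and its median position was -0.377. With only the 2 groups in the fit, Q against G gave 2553 and QxG against GxQ 1143. A minimum of 5 CPM left 7 and 4 one-parent transcripts in Q and G. With an estimated correlation 0 of the 5 list tests passed in Q against G, QxG against GxQ and both hybrids; fry called 4 lists in these, of which 2, heat shock and cell wall between the reciprocal hybrids, were among the 5. For single hybrids against the mid-parent camera called 1 list in QxG and 2 in GxQ, of which 0 passed with an estimated correlation, and fry called 2 and 6, with these 3 among them. Against the arithmetic mid-parent, CCD1A in both hybrids turned to -0.37. The median position of GxQ turned to 0.0642 without the second GxQ library. For these the cause was not tested.

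Leaving out each library in turn gave ranges of 335 to 2207 for Q against G, 1127 to 2205 for QxG against GxQ, 310 to 2606 for QxG against Q, 342 to 1993 for QxG against G, 1258 to 3828 for GxQ against Q, 777 to 3072 for GxQ against G, 368 to 2536, 1455 to 3779 and 1002 to 2663 for QxG, GxQ and both against the mid-parent, 131 to 853 and 439 to 1433 outside both parents, and median positions of -0.262 to 0.186 for QxG and -0.431 to 0.0642 for GxQ. Lowest counts came without the first G, the third GxQ, the first Q, the third G, the second Q, the second G, the third QxG, the third GxQ and the third G library in this order of comparisons, and without the third QxG and the second G library for genes outside both parents. Depth limits genes near 0: 3 counts equal 0.119 to 0.197 CPM.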

Other observations

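Each hybrid taken singly against the mid-parent was a planned comparison; list tests without single libraries and the genes named here were chosen after their values were seen.

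In QxG, 7 of 10 heat shock genes were above it and 0 below (8 and 0 adjusted over the list alone), among them HSP21 by 1.87 on the log2 scale (SE 0.358), HSP90 by 2.04 (SE 0.468) and the small heat shock gene Solyc08g062340 by 3.11 (SE 0.613), with edgeR adjusted p = 0.0119, 0.0228 and 0.0132. Camera gave adjusted p = 8.99e-07 for this list, and adjusted p = 0.737 with an estimated correlation. In GxQ, 1 was above and 1 below; the difference between the hybrids was called for 4 members. Without the third QxG library all 7 calls ended (adjusted p = 0.0619 for HSP21 at its highest over left-out libraries, 0.108 for HSP90 and 0.0782 for Solyc08g062340), and without the second 5 were called. HSP90 stood at 6373, 3755 and 9855 CPM in the QxG libraries, 806 to 1254 in GxQ, 500 to 2539 in Q and 1742 to 2932 in G.

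In GxQ, 5 of 13 cell wall genes fell below the mid-parent and 0 were above (6 and 0 adjusted over the list alone): PL by 2.32, PG2A by 1.51, EXP1 by 1.86, CEL1 by 2.52 and MAN4 by 4.93 (adjusted p = 0.000891, 0.0457, 0.0155, 0.0368 and 0.00819). Together these encode a pectate lyase, a polygalacturonase, an expansin, an endoglucanase and a mannanase. CEL1, the endoglucanase, stood near the floor, at 0.0566 to 0.493 CPM in GxQ and 0.163 to 0.769 CPM in Q. It stood at 4.81 to 7.88 CPM in G, so in GxQ it lay near the Q level. Camera gave adjusted p = 0.00899 for this list, adjusted p = 0.491 with an estimated correlation, and 0.0528 without the second GxQ library. The carotenoid list, with 3 of 21 members lower and 0 higher, also passed camera in GxQ (adjusted p = 0.00899; adjusted p = 0.491 with an estimated correlation, and 0.177 without the first GxQ library). None of the 21 was called in QxG by edgeR (7 at an unadjusted p under 0.05, 4 by DESeq2). None of the 13 cell wall genes was called in QxG by edgeR (5 at an unadjusted p under 0.05, 0 by DESeq2), and the difference between the hybrids was called for PL, EXP1 and MAN4. PL and MAN4 stayed called without each library in turn; the call ended without the second GxQ library for EXP1 (adjusted p = 0.0617) and without each of 8 libraries, all G and all GxQ among them, for PG2A and CEL1 (0.132 and 0.117 at the highest). The third Q library, high in PG2A, EXP1 and MAN4 (7549, 2060 and 155 CPM, against 1565 to 1918, 512 to 565 and 17.9 to 19.3 in the first and second), enters the mid-parent. The chloroplast list had 4 of 8 members lower in GxQ: APRR2L by 0.77, Solyc03g005760 by 1.38, PSBS by 3.79 and the stay-green gene SGR1 by 1.34 (adjusted p = 0.0158, 0.0237, 0.0111 and 0.0305); the list did not pass camera (adjusted p = 0.171), nor did its difference between the hybrids (0.133). Of these, APRR2L ended without the second GxQ library, PSBS without the third, Solyc03g005760 without the first or the second, and SGR1 without either of those or the first or the third G library (highest adjusted p = 0.0669, 0.0514, 0.0919 and 0.112). GxQ also had the ethylene genes ACS1A and ACO5 above the mid-parent by 2.02 and 2.25, and ETR4 and ACO4 lower by -1.12 and -1.09 (adjusted p = 0.0185, 0.0295, 0.0155 and 0.0293); calls ended without the second or the third GxQ library for ACS1A, without the first or the third for ETR4, and for ACO5 and ACO4 without the first or the second GxQ, the second Q, or the second or the third G library (highest adjusted p = 0.0696, 0.0662, 0.124 and 0.0951).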
